A study of Homo sapiens with 6 samples.

How the data were processed

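RNA was sequenced from 6 libraries of Ovcar8 cells, 3 treated with DMF (the control) and 3 with 1 µM cisplatin, each for 4 days. Per the labels' protocols, RNA was extracted with Trizol, cleaned on a column with a DNase step, made into libraries with the NEBNext Ultra II RNA kit and sequenced on a NovaSeq. The authors deposited raw counts per gene and library and, in a separate table, FPKM values of the same libraries. STAR 2.6.1, DESeq2 and the genome build GRCh38 are named in the submitters' processing notes, without the role of each tool. The read counter, the annotation and the strand setting are not given in the sources used here. Antisense and overlapping genes could therefore share counts.

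All 58735 gene rows of the deposited count table matched GENCODE release 29 by identifier, and gene names, types, positions and exonic lengths were taken from that release. The exonic length of a gene joins the exons of all its annotated transcripts, so it can exceed the length of each transcript. The deposited FPKM values equalled the count divided by the exonic length and by a factor per library, with lengths within 1% of the annotated ones for 100% of the genes compared. That factor was not proportional to the count totals, and its log2 offset differed by 0.117 between cisplatin and DMF. Count totals ran from 14502150 to 16112585.

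The comparison of cisplatin with DMF used edgeR 4.0.16 on the deposited counts in R 4.3.3, with TMM normalization, filterByExpr by treatment, a robust quasi-likelihood fit and a two-sided test. P-values were adjusted by Benjamini-Hochberg over the 14433 genes tested, with a threshold of 0.05. The biological coefficient of variation was 0.184. The CPM values of named genes are scaled to the library's count total over the genes tested, times its TMM factor. Those of the markers of other cell types are scaled to the library's total count, without the TMM factor. Fold changes are cisplatin over DMF on the log2 scale with their standard errors (SE).

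Gene lists (26 pathways, 4 sets of markers of other cell types and 12 landmark genes of senescence and the cell cycle, 641 symbols in all) were fixed before the data were examined, and all 641 symbols matched. The pathway lists covered p53 targets, the cell cycle, secreted factors, interferon, antigen presentation, NF-kB, histones, stress responses, DNA repair, platinum handling, lysosomes, matrix, epithelium, translation, metabolism and apoptosis. They were tested with limma 3.58.1 camera on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 26 lists. Camera asks whether a list's genes stand apart from the other genes tested. The genes named in the text were the landmark genes, the 8 largest rises and 8 largest falls among protein-coding genes past the test with a mean of at least 1 CPM and separated groups, and up to 2 members per direction and pathway list by smallest p, or the member with the smallest p where none passed. A few genes that this rule or the lists hold are not reported here.

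Also fitted, as fixed before the data were examined, were DESeq2 size factors, library size only, no count filter, a mean of at least 1 CPM, DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 1) and log2(FPKM + 0.1) with a mean FPKM of at least 0.5, no FPKM filter, the replicate number as a block, each replicate left out in turn and, for lists, an estimated correlation and fry. The fry test was read for direction: it asks whether a list's genes moved together one way, whatever other genes did. Fits added after seeing the data were counts without mitochondrial genes, removal of each library's smooth trend on exonic length and GC content, leaving out DMF replicate 2 and cisplatin replicate 1 together, and, for genomic span, holding exonic length fixed. Tables and figures were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

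The tests were tested on simulated data drawn for the 14433 genes of the comparison of cisplatin with DMF from these libraries' means and totals. In it edgeR recovered 14.9% of 67 genes changed 1.5-fold, 61.2% of 67 changed 2-fold and 93.9% of 66 changed 4-fold, with 8 false among 121 calls. Camera called 3 of 3 raised lists and 0 of 20 unchanged ones. Genes were drawn independently of each other, so this cannot show how camera behaves on lists whose genes vary together. Each gene was drawn with the same biological coefficient of variation, and no variation was shared between genes of a library. Recovery and false calls in the real libraries may therefore differ from these values. In the real libraries the estimated correlation reached 0.391, for mitochondrially encoded genes. An imposed length trend gave 2550 calls, and 0 once the trend was removed. Replicate libraries were compared for duplicates: counts differed by more than sampling noise in each pair, with a chi-square per degree of freedom of 2.45 between DMF replicates 1 and 3 and between 9.42 and 46.1 in the other pairs.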

Results

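Gene expression was measured by RNA sequencing in Ovcar8 cells, an established human ovarian cancer line, 4 days after the start of treatment with cisplatin or with DMF, which the labels name as the control. Cisplatin is a platinum drug that forms adducts on DNA. Each group held 3 libraries, whose molecule the labels give as total RNA and whose titles say total mRNA, and the cisplatin dose was 1 µM. The count total per library ran from 15160843 to 16112585 in DMF and from 14502150 to 16066180 in cisplatin. At this depth 3 counts in a library corresponded to between 0.186 and 0.207 CPM (counts scaled to the total of the library), and intervals from counts cover counting error only. The labels do not say that the replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. The labels describe the comparison as one of therapy-induced senescence, a state that was not measured here other than by transcripts.

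Cisplatin-treated cells expressed more senescence-associated secreted factor, NF-kB target, interferon-stimulated and antigen presentation transcripts, and less of the transcripts of mitosis and glycolysis, as lists by camera with a preset correlation. With a correlation estimated from the libraries none of these lists passed (adjusted p = 0.0552 for NF-kB targets, secreted factors and interferon-stimulated genes, 0.169 for antigen presentation, 0.329 for mitosis and 0.447 for glycolysis), and 4 of 16 glycolysis genes fell by themselves. Transcripts of the cytokine gene IL6 were 8.16-fold higher, those of the cell cycle inhibitor gene CDKN1A 2.02-fold higher, and those of the proliferation marker gene MKI67 1.47-fold lower. Mitochondrially encoded transcripts took 4.56% ± 0.744 of all counts in cisplatin and 2.02% ± 0.410 in DMF (mean ± SD, n = 3 each). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3303 of 14433 genes changed, of which 1713 were higher and 1590 lower in cisplatin. The balance of directions depended on the processing, with 1843 higher and 1246 lower by library size only. It was 2389 and 3090 with each library's trend on length and GC content removed. With log2(FPKM + 1), which also changed the test and the filter, it was 1214 and 1613. Of the 3303 genes, 785 rose and 377 fell at least 2-fold.

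Every cisplatin library lay on one side of every DMF library for 6048 of the genes tested (41.9%), against 10% by chance for 3 libraries against 3. The first principal component, with 54.8% of the variance of log2 CPM, separated the treatments, and the second held 25.5%. Libraries also differed within groups. Along the first axis of the variation within groups, which held 56.9% of that variation, DMF replicate 2 scored 34.10, cisplatin replicate 3 scored 31.38 and cisplatin replicate 1 scored -37.23. The number of changed genes was 1600 without DMF replicate 1, 1385 without DMF replicate 3 and 1158 without cisplatin replicate 2. It was 6218 when DMF replicate 2 and cisplatin replicate 1 were both left out, a choice made after seeing the data that kept cisplatin replicate 3. On the axis within groups the DMF libraries kept scored -19.14 and -14.96 and the cisplatin libraries 5.84 and 31.38. That fit therefore cannot tell treatment from this axis, which holds for each result given below without these 2 libraries.

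**Figure D1:**
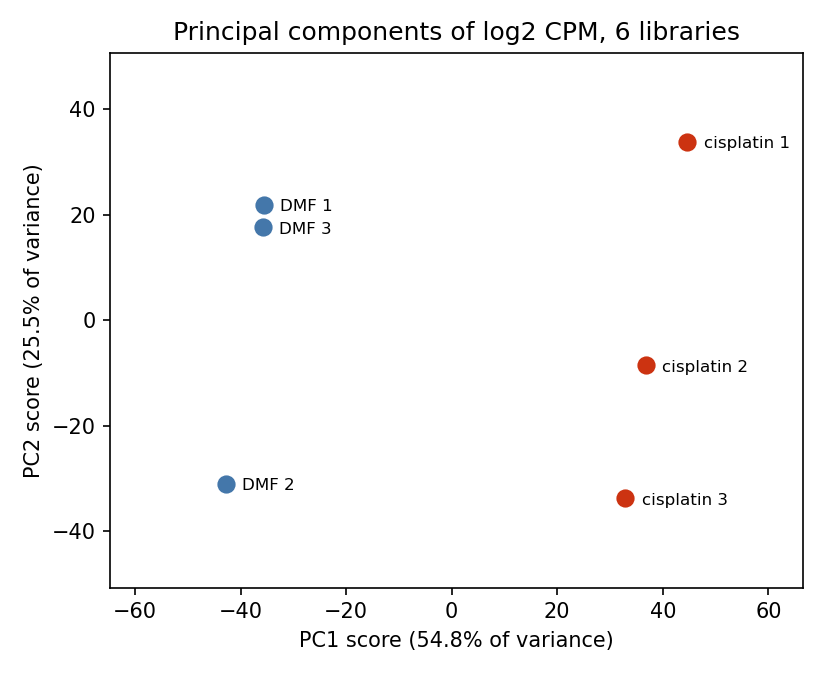
Scores of the 6 libraries on the first (horizontal axis) and second (vertical axis) principal components of log2 CPM, with DMF in blue and cisplatin in red. The first component, with 54.8% of the variance, parts the treatments, and DMF replicate 2 lies away from the other DMF libraries on the second.

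Among 12 genes chosen as landmarks of senescence and the cell cycle, 3 rose and 3 fell, with the same counts when adjusted over the list alone. CDKN1A (ENSG00000124762, GRCh38 chromosome 6, 36676460 to 36687339), which encodes the cyclin-dependent kinase inhibitor p21, rose from 36.5 ± 1.45 to 73.7 ± 5.72 CPM (SD, n = 3 each), a log2 fold change of 1.01 (SE 0.116, edgeR adjusted p = 0.00147). IL6 (ENSG00000136244, chromosome 7, 22725884 to 22732002) rose from 2.58 ± 1.01 to 21.2 ± 2.27 CPM, a log2 fold change of 3.03 (SE 0.267, edgeR adjusted p = 0.000747). The chemokine gene CXCL8 rose from 0.379 ± 0.347 to 2.77 ± 1.15 CPM, a log2 fold change of 2.88 (SE 0.623, edgeR adjusted p = 0.0143). MKI67 (ENSG00000148773, chromosome 10, 128096659 to 128126385) fell from 184 ± 6.50 to 126 ± 9.37 CPM, a log2 fold change of -0.55 (SE 0.105, edgeR adjusted p = 0.00845). The nuclear lamina gene LMNB1 had a log2 fold change of -0.46 (edgeR adjusted p = 0.0241) and the cyclin D1 gene CCND1 one of -0.47 (edgeR adjusted p = 0.0103). Without cisplatin replicate 2 the adjusted p of LMNB1, CCND1 and CXCL8 was 0.0847, 0.0579 and 0.0548. The call of LMNB1 also ended without DMF replicate 1 (0.0829) or 3 (0.0683), and that of CCND1 without DMF replicate 3 (0.0534).

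Further landmark genes did not pass the test. CDKN2A (ENSG00000147889, chromosome 9, 21967753 to 21995301), which encodes the kinase inhibitor p16, stood at 720 ± 104 CPM in DMF and 728 ± 228 CPM in cisplatin, a log2 fold change of 0.017 (edgeR adjusted p = 0.962). Its sign depended on single libraries, with a log2 fold change of -0.11 without DMF replicate 2 and -0.26 without cisplatin replicate 1. Without both it was -0.38 (edgeR adjusted p = 0.00325). These 2 libraries held its lowest DMF value (602 CPM) and its highest cisplatin value (984 CPM), so that fall follows at least in part from the choice. The log2 fold change was 0.57 for CDKN2B (edgeR adjusted p = 0.0934), 0.33 for the chromatin protein gene HMGB2 (0.102) and -0.13 for the lysosomal beta-galactosidase gene GLB1 (0.399). The ubiquitin ligase gene MDM2 differed by -0.21 (0.55). HMGB2 had a log2 fold change of 0.38 (adjusted p = 0.0408) scaled by library size only, 0.054 (0.71) with each library's trend on length and GC content removed and 0.15 (0.17) without DMF replicate 2 and cisplatin replicate 1.

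**Figure D2:**
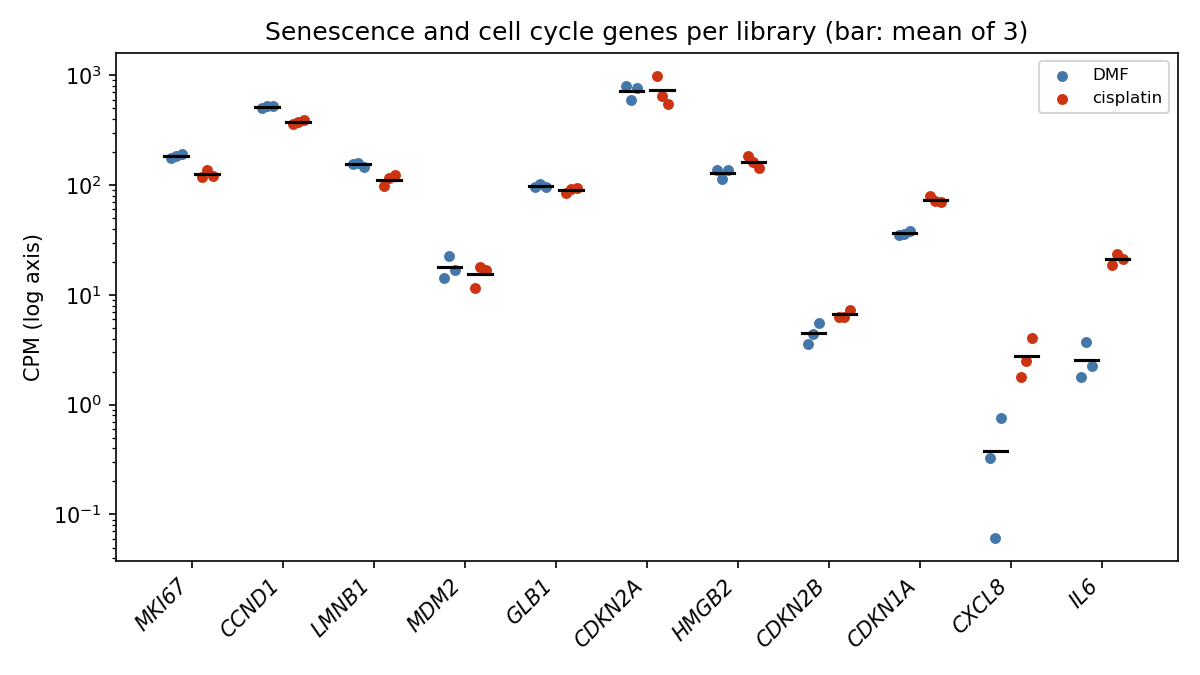
CPM on a log axis for 11 genes related to senescence and the cell cycle, ordered by log2 fold change. Points are the 3 DMF (blue) and 3 cisplatin (red) libraries and bars their means; IL6 lies between 1.77 and 3.72 CPM in DMF and between 18.9 and 23.4 CPM in cisplatin.

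The largest rises among protein-coding genes with a mean of at least 1 CPM and separated groups were in 8 genes. TMEM52B had 1 count in DMF and 143 in cisplatin over 3 libraries each, a ratio of 147 with a 95% counting interval of 26 to 5860. OLR1 (ENSG00000173391, chromosome 12, 10158301 to 10172138), a receptor for oxidised low-density lipoprotein, rose by a log2 fold change of 5.39 (SE 0.388, edgeR adjusted p = 0.000542). It had 8 counts in DMF and 352 in cisplatin over 3 libraries each, so the size of its rise rests on few DMF counts. OLR1 overlaps TMEM52B in position, so the counts of this pair could not be fully told apart. SAA1, an acute-phase protein gene, rose by 4.48, and NPPB, the gene of a natriuretic peptide precursor, by 4.07 on the log2 scale. NEURL3 rose by 3.60, SYNPO2L by 3.32 and TNFRSF9, which encodes the receptor 4-1BB, by 3.30. SAA1 has a close paralog, and U2AF1, with a log2 fold change of 3.12, has a near-identical annotated copy, so both values are uncertain. U2AF1 varied widely in cisplatin (26.7 ± 16.6 CPM) and had an adjusted p of 0.162 without DMF replicate 2 and cisplatin replicate 1.

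The largest falls by the same rule were smaller. KLHL11 had a log2 fold change of -3.82 (SE 0.702, edgeR adjusted p = 0.0077) and an adjusted p of 0.050 without cisplatin replicate 2. It had 105 counts in DMF and 7 in cisplatin over all libraries of each group, so the size of its fall rests on few cisplatin counts. The integrin alpha 4 gene ITGA4 had a log2 fold change of -2.60 and the potassium channel gene KCNJ11 one of -2.56, each past the edgeR test (adjusted p = 0.00146 and 0.00104). TTC5 (ENSG00000136319, chromosome 14, 20256558 to 20305994) fell from 37.9 ± 1.60 to 8.19 ± 1.68 CPM, the highest starting level of the 8. The remaining log2 fold changes were -2.62 for ZNF619, -2.48 for GGACT, -2.41 for the DNA helicase gene RTEL1 and -2.35 for CRYBG3. Each of these 4 genes overlaps another counted gene, as do further named genes, among them IL6, DDIT3, IFIT3, COX6C and RPS27L. ZNF619 lost its call in 5 of the 6 fits that left out 1 library, with an adjusted p of up to 0.120 (without cisplatin replicate 2), and the size of its fall rested on cisplatin replicate 1 (0.753 CPM, against 0.061 and 0.065 in the others), without which the log2 fold change was -4.66.

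Of 35 genes of G2/M and mitosis, 13 fell and 1 rose over all genes tested, and 18 fell and 2 rose when adjusted over the list alone, with a median log2 fold change of -0.44. Over all genes tested, 26 fell and 2 rose with each library's trend on length and GC content removed. The list was lower than other genes by camera (adjusted p = 0.000274, and adjusted p = 0.329 with an estimated correlation). PLK1 (ENSG00000166851, chromosome 16, 23677656 to 23690367), a mitotic kinase, fell from 420 ± 35.5 to 217 ± 20.9 CPM (log2 fold change -0.95, edgeR adjusted p = 0.00200), and CDC20, an activator of the anaphase-promoting complex, had a log2 fold change of -0.67. NUSAP1, a spindle protein gene, was the member that rose, by 0.88 on the log2 scale, with an adjusted p of 0.0785 without cisplatin replicate 2 and 0.0758 without DMF replicate 3. Of 40 genes of G1/S and DNA replication, 12 rose and 5 fell, or 13 and 10 when adjusted over the list alone, and the list did not stand apart from other genes (camera adjusted p = 0.401). With the trend on length and GC content removed 10 of these genes rose and 11 fell. The cyclin E1 gene CCNE1 rose by 0.69 and the phosphatase gene CDC25A by 0.66, while the replicative helicase genes MCM2 and MCM5 had log2 fold changes of -0.77 and -0.79. CCNE1 had an adjusted p of 0.0505 without cisplatin replicate 2.

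The NF-kB target and secreted factor lists were higher by camera with the preset correlation. Of 15 measured NF-kB target genes, 13 rose and none fell, with the same counts when adjusted over the list alone and a median log2 fold change of 1.11 (camera adjusted p = 8.43e-09, and adjusted p = 0.0552 with an estimated correlation). NFKBIE, an inhibitor of NF-kB, rose by 1.40 and the surface protein gene CD83 by 1.47. Of 26 measured senescence-associated secreted factor genes, 14 rose and 1 fell, or 18 and 2 when adjusted over the list alone, with a median of 1.03 (camera adjusted p = 6.55e-06, and adjusted p = 0.0552 with an estimated correlation). IL1B rose from 3.79 ± 0.457 to 18 ± 1.49 CPM, a log2 fold change of 2.25 (SE 0.177, edgeR adjusted p = 0.000567), and the insulin-like growth factor binding protein gene IGFBP3 was the member that fell (log2 fold change -0.51, edgeR adjusted p = 0.00859).

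The interferon-stimulated and antigen presentation lists were also higher by that test. Of 24 measured interferon-stimulated genes, 11 rose and none fell, or 13 when adjusted over the list alone, with a median log2 fold change of 0.57 (camera adjusted p = 1.25e-05, and adjusted p = 0.0552 with an estimated correlation). ISG15, a ubiquitin-like modifier gene, rose from 37.1 ± 2.55 to 80.6 ± 9.30 CPM, and IFIT3 had a log2 fold change of 2.08 (edgeR adjusted p = 0.00208). Of 17 measured genes of MHC class I and antigen presentation, 9 rose and none fell, or 11 when adjusted over the list alone, with a median of 0.50 (camera adjusted p = 2.16e-05, and adjusted p = 0.169 with an estimated correlation). HLA-B (ENSG00000234745, chromosome 6, 31269491 to 31357188), a class I heavy chain gene, rose from 547 ± 21.9 to 1529 ± 117 CPM (log2 fold change 1.48), and B2M, the gene of the class I light chain, rose by 1.41. Reads of HLA-B could be shared with related class I genes, so its value is uncertain.

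Among 25 measured p53 target genes, 6 rose and none fell, with the same counts when adjusted over the list alone and a median log2 fold change of 0.36. The list was higher than other genes by camera (adjusted p = 0.0325, and adjusted p = 0.169 with an estimated correlation). Besides CDKN1A, RPS27L rose by 1.41 on the log2 scale (edgeR adjusted p = 0.00118). The list's call ended with the FPKM values (adjusted p = 0.0881), once each library's trend on exonic length and GC content was removed (0.0516), and without DMF replicate 2 and cisplatin replicate 1 together (0.0799). Of 17 measured apoptosis regulator genes, 3 rose and 1 fell, with the same counts when adjusted over the list alone, and the list did not pass the test (camera adjusted p = 0.0787). BMF, a pro-apoptotic BH3-only gene, rose by 2.72 and PMAIP1, another, by 0.91, while BAK1, a pore-forming effector, had a log2 fold change of -0.52. Without cisplatin replicate 2 their adjusted p values were 0.0562, 0.0792 and 0.138.

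Stress response lists did not stand apart from other genes by camera, although single members moved. Of 20 ATF4 stress response genes, 3 rose and 1 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.164). DDIT3 and ATF3, both stress-induced transcription factor genes, rose by 2.27 and 2.20 on the log2 scale (edgeR adjusted p = 0.000542 and 0.000567), and ALDH1L2 had a log2 fold change of -0.98. Of 16 ER chaperone genes, 2 rose (MANF by 0.81 and DNAJB11 by 0.67) and 1 fell (SEL1L, log2 fold change -0.79), with the same counts when adjusted over the list alone (camera adjusted p = 0.249). Of 17 measured NRF2 target genes, 3 rose and 2 fell, or 3 and 3 when adjusted over the list alone (camera adjusted p = 0.593), and the list's median log2 fold change was -0.13 while its mean was 0.06. The aldo-keto reductase genes AKR1C3 and AKR1C1, near-identical paralogs whose values are uncertain, rose by 1.65 and 1.78, while GCLM, which serves glutathione synthesis, and NQO1, a quinone reductase gene, had log2 fold changes of -0.98 and -0.37. Without cisplatin replicate 2 the edgeR adjusted p was 0.139 for ALDH1L2 (0.0755 without DMF replicate 2 and cisplatin replicate 1), 0.0571 for MANF, 0.111 for DNAJB11 (as with the trend on length and GC content removed), 0.0702 for SEL1L and 0.115 for NQO1.

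Lists of DNA repair and platinum handling did not pass camera on the filtered genes. Of 19 measured nucleotide excision repair genes, 3 fell and none rose, with the same counts when adjusted over the list alone (camera adjusted p = 0.164). DDB1, part of a damage recognition complex, fell from 890 ± 22.1 to 513 ± 9.41 CPM (log2 fold change -0.80, edgeR adjusted p = 0.00152), and the DNA ligase gene LIG1 had a log2 fold change of -0.55. Of 23 measured Fanconi anaemia and homologous recombination genes, 2 rose (RAD51C by 0.80 and the exonuclease gene EXO1 by 0.71) and 2 fell (FANCA and FANCE, with log2 fold changes of -0.48 and -0.36), with the same counts when adjusted over the list alone (camera adjusted p = 0.683). Of 13 measured platinum transport and detoxification genes, 2 rose and 1 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.82), and the list's median was 0.02 while its mean was -0.10. The metallothionein genes MT1M and MT1E, close paralogs whose values are uncertain, went opposite ways, with log2 fold changes of 1.39 and -0.74, and TMEM205 rose by 0.61, or by 0.32 with the trend on length and GC content removed. Without cisplatin replicate 2 the edgeR adjusted p was 0.0801 for LIG1, 0.0650 for RAD51C, 0.0810 for FANCA, 0.147 for FANCE, 0.0592 for MT1E and 0.0840 for TMEM205.

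The lysosome and matrix lists were higher by camera with the preset correlation, while 16 members of each did not pass the edgeR test. Of 25 measured lysosome genes, 9 rose and none fell, or 12 and 1 when adjusted over the list alone, with a median log2 fold change of 0.36 (camera adjusted p = 4.87e-05, and adjusted p = 0.0552 with an estimated correlation). The sialidase gene NEU1 rose from 90.2 ± 1.62 to 178 ± 4.03 CPM (log2 fold change 0.98, edgeR adjusted p = 0.000989) and the beta-glucuronidase gene GUSB by 0.73. Of 22 measured extracellular matrix and mesenchymal genes, 6 rose and none fell, with the same counts when adjusted over the list alone and a median of 0.36 (camera adjusted p = 0.00321, and adjusted p = 0.169 with an estimated correlation). LOX (ENSG00000113083, chromosome 5, 122063195 to 122078360), which encodes a collagen cross-linking enzyme, rose by 2.00 and the fibronectin gene FN1 by 0.91. Of 14 measured epithelial and ovarian carcinoma genes, 3 rose and 1 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.442). The folate receptor gene FOLR1 rose by 2.01 and the E-cadherin gene CDH1 by 2.24, and the keratin gene KRT18 had a log2 fold change of -0.46, with an adjusted p of up to 0.0942 (without DMF replicate 3).

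The calls of the histone and ribosomal protein lists depended on the processing. Of 12 measured replication-dependent histone genes, 5 rose and none fell, or 6 when adjusted over the list alone, with a median log2 fold change of 0.88 (camera adjusted p = 0.00247, and adjusted p = 0.169 with an estimated correlation). HIST1H2BJ and HIST1H2AC each rose by 1.73, and reads of histone genes could be split between near-identical copies. The histone call ended once the trend on length and GC content was removed (adjusted p = 0.0516). Of 32 cytosolic ribosomal protein genes, 8 rose and none fell, or 9 when adjusted over the list alone, with a median of 0.10 (camera adjusted p = 0.0341, and adjusted p = 0.506 with an estimated correlation). RPL7 rose by 1.07 and RPS27A by 0.68, and both have processed pseudogenes that could share reads. With the trend removed 4 of these genes rose and 4 fell, and 12 rose and 9 fell without DMF replicate 2 and cisplatin replicate 1. The ribosomal protein call ended without DMF replicate 2 (adjusted p = 0.218), without cisplatin replicate 1 (0.25), without both (0.701), with the FPKM values (0.126) and with the trend removed (0.78). Of 31 measured translation factor genes, 5 fell and 1 rose, with the same counts when adjusted over the list alone (camera adjusted p = 0.241). EIF3A and EIF2B5 had log2 fold changes of -0.70 and -0.53 and EIF2S2 rose by 0.60, or by 0.25 with the trend removed. The calls of EIF2B5 and EIF2S2 ended without DMF replicate 3 (0.0552 and 0.0837) or cisplatin replicate 2 (0.0505 and 0.0793), and that of EIF2S2 also without DMF replicate 1 (0.0719).

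Among metabolic lists the mitochondrial genome stood out. Of its 13 protein-coding genes, 12 rose and none fell, with the same counts when adjusted over the list alone and a median log2 fold change of 1.14 (camera adjusted p = 2.4e-08, and adjusted p = 0.169 with an estimated correlation). MT-ND1, a complex I subunit gene, rose from 716 ± 97.7 to 2042 ± 383 CPM (log2 fold change 1.51, edgeR adjusted p = 0.00118) and MT-ND5 by 1.09. Reads could be shared with nuclear copies of the mitochondrial genome. Of 30 nuclear oxidative phosphorylation genes, 4 rose and 3 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.391). COX6C rose by 1.43 and NDUFB3 by 1.16, and SDHC and ATP5F1B had log2 fold changes of -0.41 and -0.37. Of 16 glycolysis genes, 4 fell and none rose, with the same counts when adjusted over the list alone and a median of -0.29 (camera adjusted p = 0.0132, and adjusted p = 0.447 with an estimated correlation). These counts depended on the fit: 8 fell and 1 rose with the trend on length and GC content removed, and 12 and 1 without DMF replicate 2 and cisplatin replicate 1. The enolase gene ENO1 and GAPDH, a gene often used as a reference, had log2 fold changes of -0.53 and -0.41. Their edgeR adjusted p values were 0.0663 and 0.0569 without cisplatin replicate 2, and those of SDHC and ATP5F1B were 0.0958 and 0.0974. With the trend on length and GC content removed SDHC had a log2 fold change of -0.23 (adjusted p = 0.0746), ATP5F1B one of -0.66 (0.000602), NDUFB3 one of 0.73 and MT-ND5 one of 0.69.

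The remaining lists did not pass camera. Of 22 nucleotide synthesis genes, 3 rose and 3 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.601). RRM2, a ribonucleotide reductase subunit gene, rose by 0.82 and PRPS1 by 0.45, or by 0.097 (adjusted p = 0.343) with the trend on length and GC content removed, and PFAS and CAD, which serve purine and pyrimidine synthesis, had log2 fold changes of -0.87 and -0.81. Of 13 measured iron handling genes, 2 fell and none rose, with the same counts when adjusted over the list alone (camera adjusted p = 0.207). These were the ferrireductase gene STEAP3, with a log2 fold change of -1.13 (edgeR adjusted p = 0.00108), and the iron regulatory protein gene IREB2, with -0.89. Of 24 measured cholesterol synthesis and uptake genes, 2 rose (IDI1 by 0.78 and MSMO1 by 0.62) and 2 fell, among them LSS with a log2 fold change of -0.62, with the same counts when adjusted over the list alone (camera adjusted p = 0.836). Without cisplatin replicate 2 the edgeR adjusted p was 0.0671 for RRM2, 0.0738 for PRPS1, 0.102 for IREB2 and 0.108 for LSS, and without DMF replicate 3 it was 0.120 for IDI1 and 0.123 for MSMO1.

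**Figure D3:**
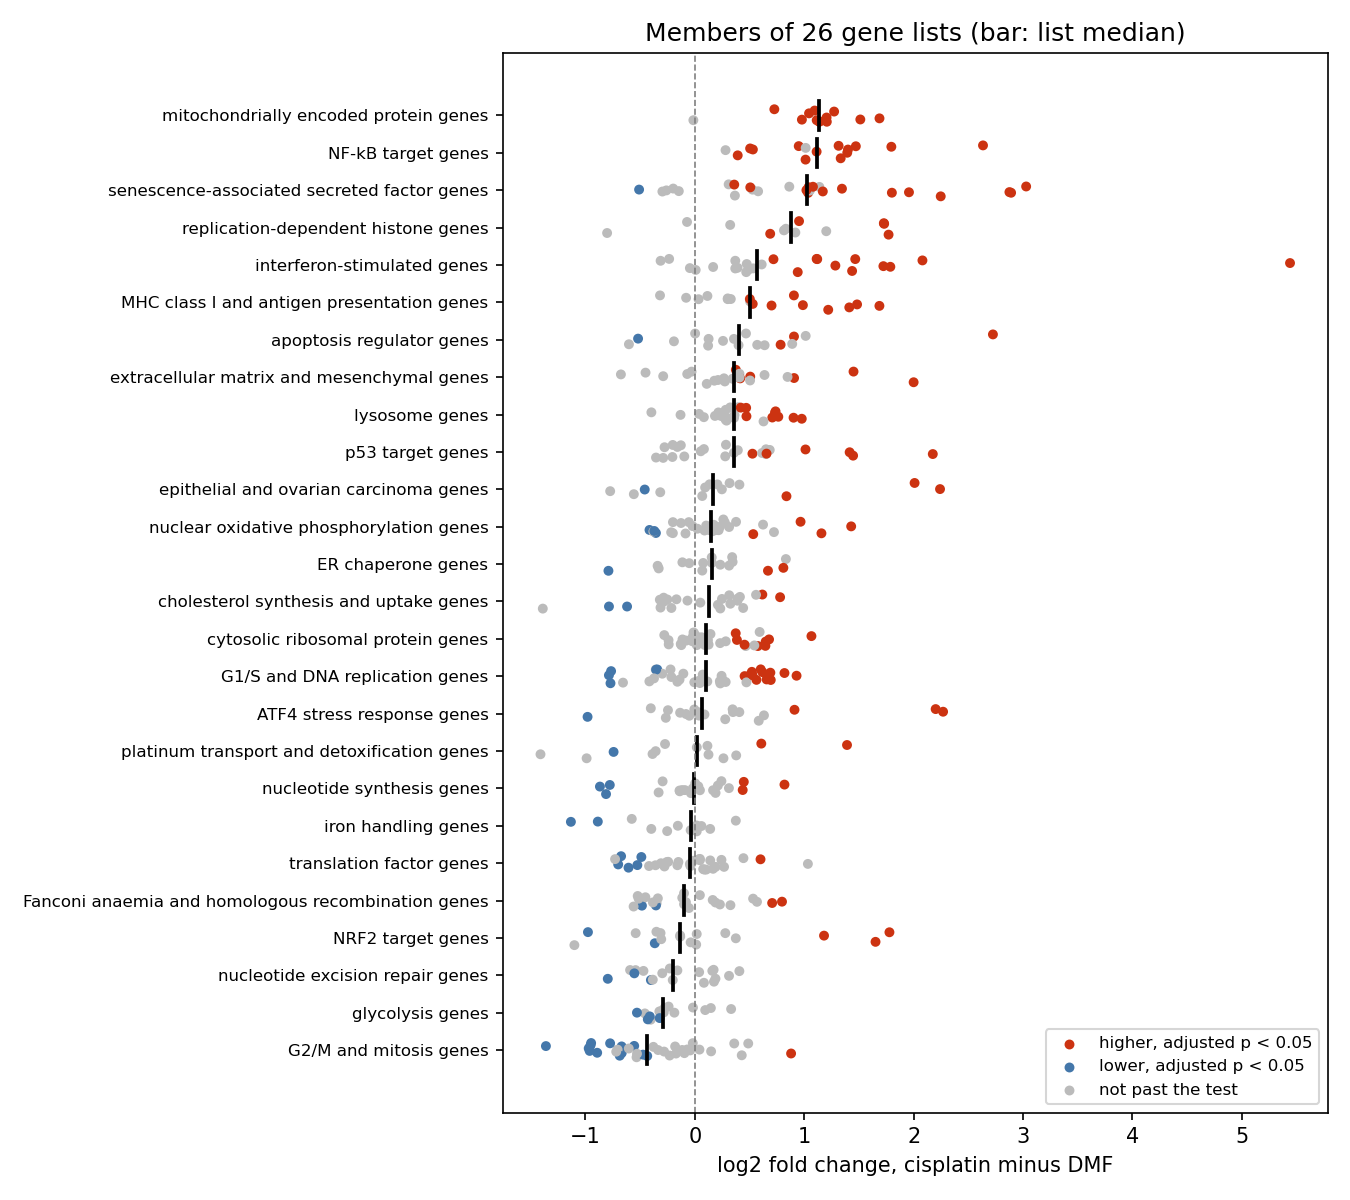
Log2 fold change (horizontal axis, cisplatin minus DMF) of each tested member of 26 gene lists, ordered by list median (black bar). Red points rose and blue points fell at an edgeR adjusted p under 0.05, and grey points did not pass; the median is 1.14 for mitochondrially encoded genes and -0.44 for genes of G2/M and mitosis.

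In all, 10 of the 26 lists were higher and 2 lower by camera with a preset correlation of 0.01. With a correlation estimated from the 6 libraries no list passed camera (lowest adjusted p = 0.0552), and 5 lists had an unadjusted p under 0.05. The estimate was -0.033 for p53 targets, -0.029 for secreted factors, -0.022 for lysosome genes and 0.008 for interferon-stimulated genes, each below the preset. A larger correlation therefore does not account for the loss of these calls. For the other lists past camera the estimate lay above the preset, from 0.032 (matrix) to 0.391 (mitochondrially encoded). Without a count filter nucleotide excision repair (adjusted p = 0.0279), translation factors (0.0396) and apoptosis regulators (0.0378) also passed camera. The fry test, read for direction, asks another question, whether the members of a list moved together one way, whatever other genes did. By it 12 lists were higher and 4 lower, among them lists that did not pass camera: ATF4 stress response (0.00643), ER chaperones, apoptosis regulators and iron handling (0.00415 each), nucleotide excision repair (0.0138) and translation factors (0.0188). The ribosomal protein (0.131) and glycolysis (0.0568) lists did not pass fry. Of the 91 named genes past the edgeR test, calls were lost for 34 without cisplatin replicate 2, 30 without DMF replicate 3, 22 without DMF replicate 1, 9 without cisplatin replicate 3, 8 without DMF replicate 2 and 4 without cisplatin replicate 1. Several genes lost their call without more than 1 of the libraries, and not each of these values is printed here. With the trend on length and GC content removed, the log2 fold change became 0.46 for CCNE1, 0.525 for MANF, -0.65 for NQO1, -0.30 for FANCA, -0.56 for FANCE, 0.42 for RPS27A and -0.006 for MDM2.

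Several features of the libraries moved with the treatment. Genes with at least 1 count numbered 20005 ± 68.7 in DMF and 20931 ± 305 in cisplatin (SD, n = 3 each). Annotated ribosomal RNA, with mitochondrial ribosomal RNA and ribosomal RNA pseudogenes included, took 0.133% ± 0.008 and 0.356% ± 0.057 of counts. Mitochondrial ribosomal RNA is also part of the share of mitochondrially encoded transcripts, so these rises are not independent of each other. Genes that rose were shorter than genes that fell, with median exonic lengths of 3415 and 6546 bases. The median log2 fold change went from 0.34 in the tenth of genes with the shortest exonic length to -0.22 in the tenth with the longest. Long non-coding genes were mostly higher: of 1079 tested, 207 rose and 17 fell, against 1432 and 1539 of 12582 protein-coding genes.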

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

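Removal of the trend on length and GC content, leaving out DMF replicate 2 and cisplatin replicate 1 together, leaving out mitochondrial genes, and holding exonic length fixed were chosen after the data were seen. Leaving out those 2 libraries set the treatments apart along the main axis of variation within groups, so that fit cannot tell treatment from the axis. Of the 96 named genes, 94 kept their direction in each fit that tested them and 53 were called in each. Of 3303 changed genes, DESeq2 called 3281 and limma-voom 3223, all in the same direction. The number of changed genes was 1603 (754 higher, 849 lower, 286 by at least 2-fold) with unfiltered FPKM, and 336 changed by at least 2-fold on the log2(FPKM + 1) scale. It was 5479 (3090 lower) with the trend removed and 6218 (3075 higher, 3143 lower) without DMF replicate 2 and cisplatin replicate 1; the cause was not tested. With each library left out in turn, it ranged from 1158 to 3442 (663 to 1699 higher, 495 to 1743 lower, 668 to 1270 by at least 2-fold), and the lists ranged from 9 to 10 higher with 2 lower. With an estimated correlation 0 lists were higher and 0 lower by camera (5 at an unadjusted p under 0.05), and 4 were lower with fry, which tests against no change in place of other genes, and 4 by camera without a count filter; the cause was not tested. The correlation of fold change with genomic span (rho = -0.228 across genes) was -0.046 with exonic length held fixed and -0.059 without those 2 libraries, and -0.285 to -0.129 with each library left out; the cause was not tested.

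Reversed signs concerned results that had not passed the test with all libraries, and their cause was not tested. The log2 fold change of CDKN2A was -0.014 without a count filter, -0.018 with limma-voom, -0.089 and -0.090 with FPKM (pseudocounts 1 and 0.1), -0.089 with unfiltered FPKM, -0.017 with the replicate block and -0.378 (adjusted p = 0.00325) without DMF replicate 2 and cisplatin replicate 1. It ranged from -0.26 to 0.18 with each library left out. That of MDM2 was 0.174 without those 2 libraries. Adjusted p values of lists that turned direction were 0.976 (G1/S) and 0.78 (nuclear oxidative phosphorylation) with the trend removed, 0.786 (cholesterol) without a count filter, 0.826 (NRF2) with fry and 0.791 (platinum) with FPKM. Without those 2 libraries they were 0.922 for cholesterol, platinum, nuclear oxidative phosphorylation and nucleotide synthesis, 0.585 for Fanconi anaemia and 0.859 for epithelial genes. With each library left out they ranged from 0.798 to 0.999 for cholesterol, 0.662 to 0.941 for platinum and 0.394 to 0.976 for Fanconi anaemia. No clear pairing by replicate number was seen, though so few libraries cannot exclude it. Deviations of same-numbered libraries correlated at 0.447, 0.155 and -0.287. DMF replicate 1 correlated best with cisplatin replicate 1, and DMF replicate 2 with cisplatin replicate 3 (0.508). With the replicate number as a block 3671 genes changed (1857 higher, 1814 lower, 1214 by at least 2-fold), and of the named genes FANCE lost its call (adjusted p = 0.0681). Genes that did not pass are not shown to be unchanged: in simulated data 14.9% of 1.5-fold changes were recovered. Those data had far fewer changed genes, and so a stricter threshold, and the same biological coefficient of variation for each gene.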

Other observations

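The tests of length and GC bias between libraries, of the gene lists and long non-coding genes with that trend removed, of low level and short length and of overlapping genes for the long non-coding genes, and the fits without DMF replicate 2 and cisplatin replicate 1 and with exonic length held fixed, were chosen after the results were seen. Markers of other cell types were at low levels, with exceptions. Of 12 melanocytic markers, 3 reached 1 CPM in any library, and of these PMEL went from 3.03 ± 0.53 to 11.8 ± 0.91 CPM (SD, n = 3 each), MITF from 2.44 ± 0.09 to 4.37 ± 2.13 and EDNRB from 2.40 ± 0.13 to 2.95 ± 0.56. MLANA, TYR, TYRP1 and DCT, which pigment cells and many melanoma lines express, stayed at or below 0.21 CPM in each library, which argues against reads from a melanoma line, named in the series title, in these libraries. Of 7 leukocyte markers 2 reached 1 CPM (CD14 and LAPTM5, up to 1.45), as did 3 of 6 endothelial markers (VWF, TEK and CLDN5, up to 1.59). Of 6 fibroblast markers, PDGFRB stood at 30 ± 2.66 CPM in DMF and 48.9 ± 5.23 in cisplatin, and the collagen gene COL1A1 at 658 ± 19.8 and 820 ± 43.7.

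The real grouping gave 3303 changed genes by edgeR. The other 9 of the 10 splits of the 6 libraries into 3 and 3 gave at most 0, so the real grouping was 1 of 10, and 10 splits are too few for a share under 0.05. At an unadjusted p under 0.05, the split of DMF replicates 1 and 3 with cisplatin replicate 1 from the rest gave 2542 genes against 5498 for the real grouping, which points to the structure within groups.

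Fold changes fell with genomic span (Spearman rho = -0.228 across genes, which are not independent replicates), and in the same-numbered pairs (-0.283, -0.289 and -0.013; all 9 pairs of cisplatin and DMF libraries ran from -0.381 to 0.017), which met the values set beforehand for a block of transcription by adducts in long genes. The conditions that left this open were added after those values were seen: libraries of the same treatment differed along span by up to 0.339 in absolute rho, as large as the contrast itself, which is what a length and GC bias between libraries needs. The rho was -0.046 with exonic length held fixed and -0.059 without DMF replicate 2 and cisplatin replicate 1. Among replicates, span correlated with the difference of DMF replicate 2 from 1 (0.288) and of cisplatin replicate 3 from 1 (0.339). Leaving out these 2 libraries thus made rho weaker by their choice, and no conclusion is drawn from that value. With exonic length the fold change had a rho of -0.288 (-0.186 with span held), negative in all 9 cisplatin and DMF pairs (-0.356 to -0.082), and replicate libraries differed by up to 0.254, which is below the contrast but of similar size. Blocked transcription along span and library bias along exonic length stay open, as does an effect of cisplatin on gene length classes, because 3 libraries per group leave a spread between replicates near the size of the trend.

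The length and GC trend could also have produced the calls of gene lists. With each library's trend on exonic length and GC content removed, 9 of the 12 lists past camera kept their call and direction, which argues against the trend as their whole cause. Their medians before and after were -0.44 and -0.49 (G2/M), 1.03 and 0.82 (secreted factors), 0.57 and 0.48 (interferon), 0.50 and 0.41 (antigen presentation), 1.11 and 1.09 (NF-kB), 0.36 and 0.38 (lysosome), 0.36 and 0.28 (matrix), -0.29 and -0.26 (glycolysis, adjusted p = 0.0132 and 0.0486, close to the threshold) and 1.14 and 0.74 (mitochondrially encoded, SD 0.40 in both). The ribosomal protein list lost its call (adjusted p = 0.78) as its median went from 0.10 (SD 0.33) to -0.03 (SD 0.34), which is what the trend as its source needs. Its median exonic length was 3667 bases with the exons of all annotated transcripts joined, so the trend removed is not one on transcript length. The p53 target list (median 0.36 and 0.20, mean 0.41 and 0.34, SD 0.62 in both, 6 and 8 members higher, 0 and 2 lower) and the histone list (median 0.88 and 0.48, SD 0.76 and 0.73) ended just past the threshold (adjusted p = 0.0516 each) with much of the median left, so for these 2 lists the trend and an effect of cisplatin cannot be told apart.

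Of 1079 long non-coding genes tested 207 were higher and 17 lower in cisplatin, with a median log2 fold change of 0.46, or 0.25 with the length and GC trend removed (-0.02 and -0.05 for protein-coding genes). Genomic DNA in the cisplatin libraries would raise silent genes too, but the summed CPM per kb of 386 olfactory receptor genes did not rise (0.0225 in DMF, 0.0192 in cisplatin), a change of -0.289% of the median rise of the long non-coding genes called higher (1.12 CPM per kb). Coding genes matched on level and exonic length had a median of 0.26, so low level and short length left 0.20 unaccounted for, and none of 100 matched draws exceeded 0.34. The 518 long non-coding genes with no recorded overlap with a gene of a mean of 10 counts had a median of 0.55, 0.28 above their matched coding genes. Overlaps were recorded only between genes that each had a mean of 10 counts. The set may therefore hold long non-coding genes below that level that do overlap another gene. These values thus cannot decide whether reads from overlapping genes took part. A hypothesis that stays open is an effect of cisplatin on non-coding transcription, while the removed trend went with part of the rise and unspliced RNA was not tested.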
